A study of Mus musculus with 20 samples.

How the data were processed

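Gene counts and miRNA family counts from wild-type mouse testis and purified spermatocytes were analysed as the authors deposited them, in a table per assay with a column per library. Per the submitters' processing notes, BWA 0.7.8, Bowtie 0.12.7, HTSeq 0.6.1 and edgeR 3.6.8 were used with the mm9 genome; which tool made which table, and the trimming and mapping settings, are not given in the sources used here. Per the labels' protocols, RNA was extracted with TRIzol, libraries were made with TruSeq kits, and the purity of the adult fractions was judged by microscopy. Both tables as deposited hold raw counts, as whole numbers with a different total per library. The RNA table holds 23366 gene symbols and 5 summary categories of HTSeq, which were kept out of library sizes and tests; they held 44.7% to 64.5% of the reads per library. Strand use in the counting is not given, so reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies are uncertain.

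The small RNA table holds 4940 seeds of 7 bases. Names were given to 101 of them from the mature sequences of well-known mouse miRNAs, taken as positions 2 to 8; these sequences were compiled from general knowledge after the table had been seen, and a seed names a family, not a single miRNA or arm. The named seeds covered 87.63% to 92.51% of counts. Some unnamed seeds are a named seed shifted by a base, such as CCCUGUA beside ACCCUGU of miR-10. Rows are thus not all separate families, and counts of families below are counts of rows. Chromosomes were taken from a RefSeq gene table of GRCm38.p6, which matched 23220 of 23366 symbols (99.4%), 1028 of them on the X. As the authors' build differs, no coordinates are given. Sites of miRNA seeds in transcripts were not analysed here, since 3′ ends were not used here.

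Samples fell into 5 stages with 2 replicates per assay, and 4 comparisons of consecutive stages were made per assay. The tests, gene lists, rule for named genes and other settings to try were set before the data were examined. Genes were kept by edgeR's filterByExpr with a minimum count of 10, leaving 16872 genes and 745 families. Libraries were scaled by TMM and all 10 libraries of an assay were fitted together with edgeR 4.0.16 (R 4.3.3), which leaves 5 residual degrees of freedom. The quasi-likelihood F test was two-sided, with Benjamini-Hochberg adjustment at 0.05; standard errors are the absolute log2 fold change over the square root of F. CPM use TMM-scaled library sizes. A fold against a group at 0 counts is a lower bound taken at 3 counts over the group, and with 1 to 3 counts the ratio has an exact 95% interval. Such intervals and floors cover counting error only. A floor of 3 counts was 0.135 to 0.834 CPM per RNA library and 0.271 to 26.6 CPM per small RNA library.

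The 20 gene lists (cell types, germ cell stages and pathways) and 23 miRNA lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry. The miRNA lists that hold a single family were not tested as lists and rest on the test of that family. Members were also counted adjusted over the list alone. A pair of further lists for checks and the choice of lists described at each step were fixed after the files had been seen but before any test was run. Named were the 5 largest rises and falls per RNA step past the test, of at least 10 CPM in the higher group and with libraries that do not overlap, the 6 largest per small RNA step at 100 CPM, up to 4 members with the largest change per list described, and a fixed set of genes and families. Other members named beside a list (Lin28b, Pdha2, Rpl39l, Vwf, Sox17, Id4, Hsd3b6, Insl3, Col2a1, miR-18, miR-19, miR-26-5p, miR-221 and miR-222) were chosen after their values were seen.

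The test was tried on simulated counts drawn from the fitted means and library sizes and a spread common to all stages, with 200 genes or 60 families changed. In each step the later stage was given the means of the earlier stage before these changes. Recovery and scaling were thus not tried where most genes change at once, as from day 7 to leptotene/zygotene. Replicates varied more in the spermatocyte stages than in the testis stages, so recovery in the data may differ from these shares. In the RNA steps 57% to 68% of the 4-fold changes and 3% to 7.07% of the 2-fold changes were recovered. In the small RNA steps 4-fold changes were recovered at 59.3%, 46.7%, 22.2% and 16.7% in the order of the stages, and 2-fold changes at 3.57% to 10%. No replicate pair was alike within sampling noise. Alternatives were DESeq2 1.42.0, its size factors or upper-quartile factors in the same fit, no filter, only the stages compared, a test against a 2-fold minimum, the replicate number as a block, scaling without the 3 most abundant families, and each library left out in turn. Where a library was left out, the remaining one of its stage was assumed to vary like the other stages. Plain library sizes, a fit of the testis stages alone, thinning of the small RNA libraries, leaving out both spermatocyte libraries with the same number, pachytene against day 7 and the refits of named genes were added after seeing the data. Upper-quartile factors were planned for the counts of genes and families but not for the lists or the X-linked genes.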

Results

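RNA and small RNA were sequenced from wild-type C57BL/6J mouse testes at 5 stages. The first 3 were whole testis on days 1, 3 and 7 after birth, and the others were leptotene/zygotene and pachytene spermatocytes purified from adults aged 70 to 80 days by sedimentation at unit gravity, which parts cells by size. Each stage had 2 biological replicates per assay, giving 10 RNA libraries and 10 small RNA libraries. Leptotene and zygotene are the early stages of meiotic prophase, in which chromosomes break, pair and synapse, and pachytene follows them. A whole testis also holds Sertoli, Leydig, peritubular, endothelial and blood cells, whereas the purified fractions were enriched for a germ cell stage, so the step from day 7 to leptotene/zygotene compares a mixed tissue with purified cells.

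Reads counted on genes came to 6133551 and 8525886 in the day 1 replicates, 22181395 and 9427526 at day 3, 13247563 and 11813196 at day 7, 3597360 and 20545793 in leptotene/zygotene, and 6423696 and 9280910 in pachytene. The small RNA counts were more uneven, at 1421742 and 2200358 on day 1, 11061273 and 8511122 on day 3, 3392587 and 8591736 on day 7, 820461 and 119746 in leptotene/zygotene, and 338443 and 112967 in pachytene. Between replicates, log2 levels of small RNA families differed with an SD of 2.24 in leptotene/zygotene and 2.31 in pachytene, against 0.463 to 0.887 in the testis stages. In the RNA assay the same SD was 1.29 and 1.08 in the spermatocyte stages and 0.361 to 0.709 in the testis stages. Levels below are CPM, counts scaled to a common library size, ± SD of 2 libraries, and log2 fold changes carry their standard error.

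The first comparison followed the testis from day 1 to day 3, the days in which the prenatal germ cells (gonocytes) return to division. Amh, the Sertoli cell hormone that regresses the female ducts, was at 935 ± 20.9 CPM on day 1 and 980 ± 358 on day 3, and Hsd3b1, a steroid-making enzyme of Leydig cells, at 500 ± 3.02 and 336 ± 70.6. Stra8, which gates entry into meiosis, was at 1.5 ± 0.20 and 2.44 ± 1.15 CPM. The 31 cell cycle genes had a median log2 fold change of 0.43 towards day 3 without a member past the test; the most abundant were Ccnd2 (-0.12 ± 0.68) and Mki67 (-0.01 ± 0.46).

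No gene passed the edgeR test between days 1 and 3 (0 of 16872), while 1088 had an unadjusted p under 0.05 and DESeq2 called 75. Leaving out the second day 3 library raised the count to 35. As a set against other genes, the cell cycle list lay higher on day 3 (camera adjusted p = 1.3e-09; adjusted p = 0.342 with an estimated correlation), as did the Sertoli (0.0128), peritubular myoid (0.00847) and macrophage (0.0116) lists. The endothelial list lay lower (median -0.46, adjusted p = 0.00106), with Cdh5, a vascular cadherin, at -0.46 ± 0.69. Each of these 4 had an adjusted p of 0.642 or 0.663 with an estimated correlation, and each was lost without a library: endothelial and macrophage without the first day 1 library, peritubular and Sertoli without the second, and all but endothelial without the first day 3 library. The spermatid list also lay lower on day 3 (median -1.19, adjusted p = 6.83e-06; adjusted p = 0.663 with an estimated correlation); this was lost without the first day 3 library (adjusted p = 0.297). Prm1, the sperm protamine, was at 4.11 ± 0.05 CPM on day 1 and 1.60 ± 2.22 on day 3. The piRNA pathway (adjusted p = 0.00886) and crossover and pachytene (0.00894) lists lay lower too, with an adjusted p of 0.663 for both with an estimated correlation, and both were lost without the first day 3 library or the second day 1 library. The miR-29 targets outside the matrix lay lower as well (0.0498; adjusted p = 0.702 with an estimated correlation), which was lost with median-ratio or upper-quartile factors and without any 1 of the day 1 or day 7 libraries or the first day 3 library. No member of the retinoic acid, DNA methylation, spermatogonia, Leydig, matrix, erythroid or miRNA machinery lists passed the test.

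From day 3 to day 7 some transcripts of spermatogonia and of germ cells about to enter meiosis rose. Stra8 went from 2.44 ± 1.15 to 44.9 ± 10.3 CPM (log2 fold change 4.24 ± 0.46, adjusted p = 0.00947). Sox3, a transcription factor of spermatogonial progenitors, rose by 4.86 ± 0.52, and Neurog3, a marker of the same cells, by 4.44 ± 0.53 to 5.83 ± 0.44 CPM. Grik3, a glutamate receptor subunit (3.91 ± 0.77), and Cacng5, of the calcium channel gamma family (3.80 ± 0.43), were also among the largest rises. Sycp3, a component of the chromosome axis, went from 2.55 ± 0.73 to 17.9 ± 0.41 CPM, and Piwil1, the PIWI protein of later spermatocytes, from 1.07 ± 0.10 to 4.95 ± 0.65. Falling genes included Ccl17, a chemokine (-5.50 ± 0.54), Pnmt, the enzyme that makes adrenaline (-5.33 ± 0.72), Cnga1 (-4.02 ± 0.51), Cbln1 (-3.28 ± 0.32) and Tpsb2, a mast cell tryptase (-3.10 ± 0.50).

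Of the 29 spermatogonial genes tested, 7 rose and none fell (15 adjusted over the list alone), with a median of 1.86. Dmrtb1, which controls the choice between mitosis and meiosis, rose by 4.09 ± 0.59, Sohlh1 by 2.85 ± 0.45 and Tex14, needed for the bridges between germ cells, by 2.60 ± 0.39. Of 37 meiotic prophase genes, 7 rose (18 adjusted over the list alone), among them Tex11 by 2.92 ± 0.58 and Gm1564, also called Meioc, by 2.45 ± 0.36. Of 23 genes of the piRNA pathway, which silences transposons with small RNAs, 11 rose (20 adjusted over the list alone, where 1 also fell), such as Henmt1 by 3.17 ± 0.37, Tdrd1 by 2.29 ± 0.37 and Mov10l1 by 2.25 ± 0.35. Crabp1, a retinoic acid binding protein, rose by 3.36 ± 0.37 (2.78 ± 1.01 to 28 ± 4.78 CPM), alone among 19 genes of retinoic acid signalling. Lin28b, from the list of 19 miRNA machinery genes, and the testis retrogenes Pdha2 and Rpl39l, from a list of 10, also passed. Other germ cell genes fell short of the threshold, including Zbtb16 (2.91 ± 0.71, adjusted p = 0.0838), Kit (1.92 ± 0.49, adjusted p = 0.0953) and Dnmt3b (1.63 ± 0.35, adjusted p = 0.0604). Dmc1, the meiotic recombinase, was at 6.19 ± 0.24 and 10 ± 0.10 CPM (adjusted p = 0.555).

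Among somatic markers, Krt18, a keratin on the Sertoli list, fell by 2.35 ± 0.44, and no Leydig, peritubular, matrix, endothelial, macrophage or erythroid marker passed the test over all genes. The 24 extracellular matrix genes had a median of -0.74 (camera adjusted p = 5.19e-06; adjusted p = 0.338 with an estimated correlation), with 5 lower when adjusted over the list alone; Col1a1, the main chain of type I collagen, was at 2706 ± 367 and 1159 ± 16.6 CPM (adjusted p = 0.226). The endothelial list was lower as well (adjusted p = 0.000454; adjusted p = 0.338 with an estimated correlation). The meiotic prophase list was higher by camera (adjusted p = 2.05e-19) and stayed past the threshold with an estimated correlation (adjusted p = 0.0484). The spermatogonial (1.68e-18) and piRNA (2.42e-26) lists each had an adjusted p of 0.107 with an estimated correlation. The miRNA machinery (0.00114) and retrogene (0.0038) lists were also higher, and the matrix targets of miR-29 (0.00114), Leydig (0.0313), macrophage (0.0373) and spermatid (0.0206) lists lower. With an estimated correlation the adjusted p was 0.563 for macrophage, 0.673 for spermatid and 0.338 for the other 4. The miRNA machinery, retrogene, Leydig and macrophage calls were lost without the first day 3 library, and the spermatid and miR-29 calls without the second. Leydig and macrophage were also lost without the first day 7 library, spermatid without the second, and macrophage without either day 1 library.

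In all, 250 of 16872 genes passed the edgeR test between days 3 and 7, 155 higher and 95 lower, and 2389 had an unadjusted p under 0.05. Without either day 7 library no gene passed, without either day 1 library 48 did, without the first day 3 library 74 (12 higher, 62 lower), and without the first or second leptotene/zygotene library 567 or 609. A fit of the testis stages without the spermatocytes, chosen after seeing the data, called 2168 (1026 higher, 1142 lower), and DESeq2 called 965 (411 higher, 554 lower). The calls of Stra8, Cacng5, Ccl17, Cnga1, Cbln1 and Crabp1 were lost in none of the other leave-one-out fits; those of the other genes named here as passing and refitted one by one were also lost without at least 1 day 1 or day 3 library, and those of Grik3 and Tex11 with median-ratio or upper-quartile factors.

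**Figure D1:**
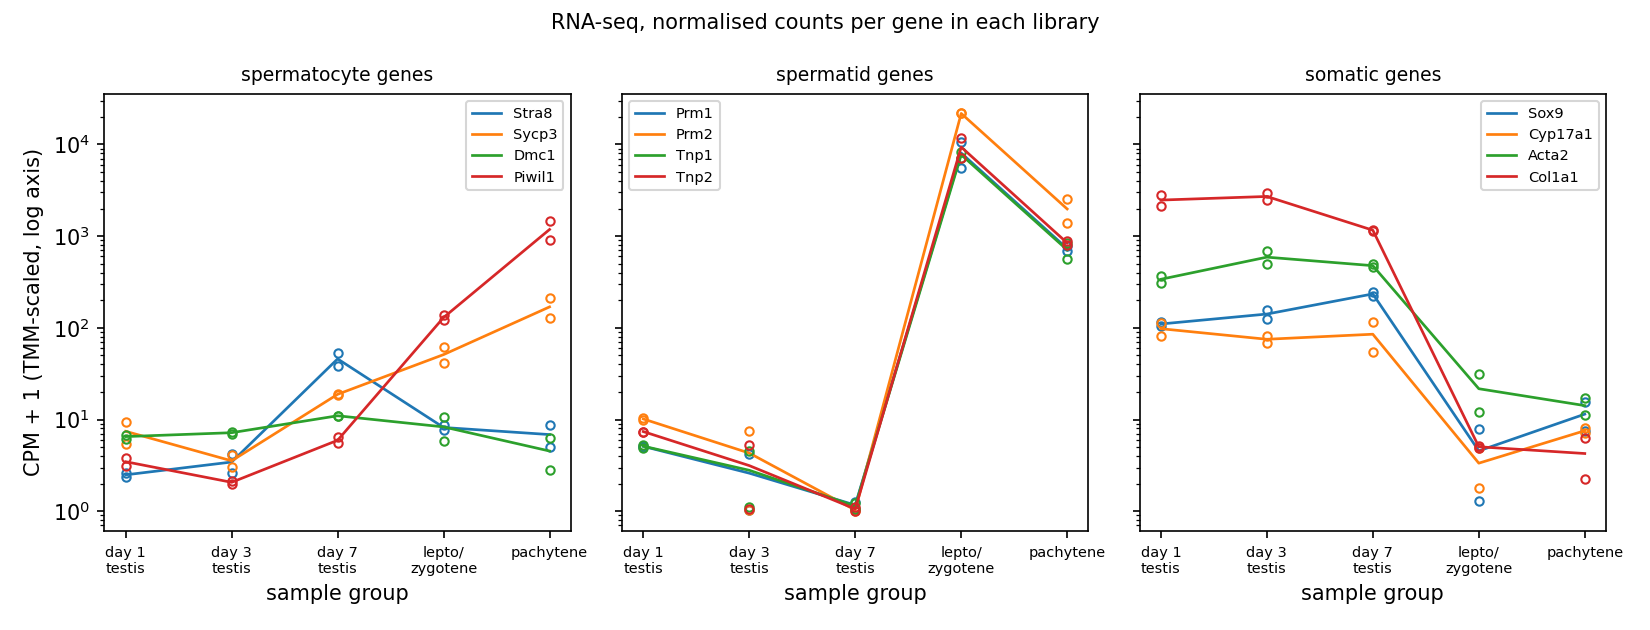
Levels of 12 transcripts at the 5 stages in 3 panels, as CPM + 1 on a log axis; open circles are single libraries (2 per stage) and lines join the stage means. Piwil1 was highest in pachytene (1181 CPM), Prm1 in leptotene/zygotene (8051 CPM), and Sox9, Cyp17a1, Acta2 and Col1a1 were lower in the spermatocyte libraries than at any testis stage.

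Leptotene/zygotene spermatocytes differed from the day 7 testis in most genes. Most of the listed genes of meiotic and later germ cells rose, and most of those of spermatogonia, Sertoli cells, Leydig cells and the extracellular matrix fell. Piwil1 went from 4.95 ± 0.65 to 129 ± 11.9 CPM (log2 fold change 4.70 ± 0.33, adjusted p = 1.56e-06), and Tdrd6, a scaffold of germ cell RNA granules, rose by 12.67 ± 0.93. Amh fell by 9.23 ± 0.56 (433 ± 3.96 to 0.45 ± 0.64 CPM), Hsd3b1 by 8.58 ± 0.43 and Col1a1 by 8.14 ± 0.61. Most of the largest rises were of genes that had no count at day 7: Spz1 was at least 85400-fold higher and Crisp2, a sperm head protein, at least 54100-fold, measured against 3 counts over both day 7 libraries, as were 4930571K23Rik (at least 52900-fold) and 4922502D21Rik (at least 40900-fold). Genes without a count in leptotene/zygotene included Oaf (at least 176-fold lower), Agtr2, an angiotensin receptor (141-fold), Lfng, a Notch modifier (114-fold), Pla2g4a (109-fold) and Col9a2 (108-fold), each a lower bound.

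Of 37 meiotic prophase genes, 22 rose and 8 fell (23 and 8 adjusted over the list alone). Syce1, of the synaptonemal complex, rose by 5.36 ± 0.44, Spo11, which makes the meiotic breaks, by 5.86 ± 0.86 and Ccdc79, also called Terb1, by 5.01 ± 0.37. Stra8 fell by 2.67 ± 0.44, to 7.20 ± 0.83 CPM, and Dmc1 was at 7.32 ± 3.41 CPM (-0.56 ± 0.48, adjusted p = 0.305; with plain library sizes it was lower, adjusted p = 0.0062). Sycp3 rose by 1.5 ± 0.39, a call lost without either day 7 library and with plain library sizes. The list was higher by camera (adjusted p = 0.0476; adjusted p = 0.419 with an estimated correlation), which was lost with median-ratio factors and without either day 3 library, the second day 7 library or the first leptotene/zygotene library. Of 23 piRNA genes 14 rose and 3 fell, the same numbers when adjusted over the list alone, with Mael at 4.88 ± 0.48, Ddx25 at 5.82 ± 0.46 and Piwil4, the PIWI protein of gonocytes, at -4.95 ± 0.89 (ratio 0.0293, counting interval 0.00353 to 0.107); its camera call (adjusted p = 0.0476; adjusted p = 0.542 with an estimated correlation) was also lost with each other scaling and without the second day 7 or either leptotene/zygotene library. Of 29 crossover and pachytene genes 24 rose and 2 fell in both counts (median 6.50, adjusted p = 7.39e-08; adjusted p = 0.217 with an estimated correlation), among them Ldhc, the testis lactate dehydrogenase (14.52 ± 1.27), and Pgk2, the testis phosphoglycerate kinase (14.97 ± 1.58).

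All 32 spermatid genes tested rose, in both counts, with a median of 12.61, or 11.8 with the 5 genes at 0 counts set at their bound (camera adjusted p = 2.11e-15; adjusted p = 0.217 with an estimated correlation). These genes act after meiosis, in shaping the sperm head and tail. Prm2, the other protamine, was at 21760 ± 26.3 CPM against 1 count at day 7 (ratio 749000, counting interval 134000 to 29600000). Tnp1, a transition protein that replaces histones, was at 7713 ± 909 CPM, and Prm1 at 8051 ± 3608. Beside these levels, macrophage markers moved in both directions, while of 3 erythroid markers 2 rose and none fell. Hemgn, named for blood progenitors, rose by 9.67 ± 0.62 to 103 ± 3.91 CPM, and Aif1, known from macrophages, by 8.20 ± 0.35 to 506 ± 150, while 10 of the other macrophage markers fell (Lyz2 by 4.21 ± 0.61).

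Most markers of the other testis cells fell, with the same counts when adjusted over the list alone unless given. Of 22 Sertoli genes 21 fell (Sox9 by 6.81 ± 0.95, Gata4 by 6.80 ± 0.59), of 14 Leydig genes 12 (Cyp17a1 by 5.71 ± 0.66), of 24 matrix genes 23 (Col3a1 by 7.64 ± 0.43, Eln by 7.83 ± 0.56), and of 15 endothelial genes 11, with Vwf and Sox17 higher. Of 12 peritubular genes 9 fell (Acta2, smooth muscle actin, by 4.61 ± 0.48), and Actg2, the other smooth muscle actin, rose by 4.91 ± 0.32 to 498 ± 119 CPM. Of 29 spermatogonial genes 21 fell (23 adjusted over the list alone), including Zbtb16 by 3.61 ± 0.79, Kit by 2.77 ± 0.54 and Neurog3, at least 23.3-fold lower, while Dmrtb1 rose by 6.42 ± 0.60 and Tex14 and Id4 rose. By camera the Sertoli (adjusted p = 1.26e-07), Leydig (0.000169), matrix (2.78e-10) and spermatogonial (0.0143) lists were lower, and with an estimated correlation the adjusted p was 0.321, 0.217, 0.217 and 0.504; the spermatogonial call was lost with plain library sizes. The peritubular list passed narrowly (0.0492; adjusted p = 0.488 with an estimated correlation), a call lost with each other scaling and without either day 1 library or the second leptotene/zygotene library, and the endothelial list did not pass (0.133). Of 31 cell cycle genes 9 rose and 13 fell, of 19 retinoic acid genes 3 rose and 15 fell, and of 19 miRNA machinery genes 5 rose and 8 fell, with Dicer1, the enzyme that cuts miRNA precursors, down by 3.41 ± 0.62 and Tarbp2, its partner, up by 2.90 ± 0.30.

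Of 21 DNA methylation genes 12 fell and 5 rose. The de novo methyltransferases Dnmt3a and Dnmt3b fell by 4.73 ± 0.50 and 3.65 ± 0.42, and Tet2 and Tet1, which oxidise methylcytosine, by 5.54 ± 0.77 and 4.89 ± 0.59, whereas the cofactor Dnmt3l rose by 4.85 ± 0.86. These 4 falling genes are also on a list of 32 genes described as targets of miR-29 outside the matrix, of which 22 fell and 3 rose (median -3.53, adjusted p = 0.00378; adjusted p = 0.488 with an estimated correlation), including Mycn by 6.29 ± 0.55 and Trib2 by 6.39 ± 0.68. Of 22 matrix targets of miR-29, 21 fell and Col2a1 rose (median -5.13, adjusted p = 4.83e-08; adjusted p = 0.217 with an estimated correlation).

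Genes on the X chromosome fell more often than autosomal genes at this step. Of 686 tested, 439 fell and 146 rose, so 64.0% fell against 41.0% of 16112 autosomal genes, and the medians were -2.84 and -0.23. The set was lower by camera (p = 0.000494; p = 0.535 with an estimated correlation). Of 34 housekeeping and germ cell genes of the X fixed as a list, 29 fell. Pgk1, the X-linked parent of Pgk2, fell by 2.02 ± 0.64, a call lost without the second leptotene/zygotene library. It was low at both stages, at 4.02 ± 0.31 CPM (138 counts) at day 7 and 1.47 ± 1.37 CPM (10 counts) in leptotene/zygotene. Of 10 autosomal retrogenes with X-linked parents 9 rose (camera adjusted p = 0.000482, and 0.308 with an estimated correlation).

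In total 13238 of 16872 genes passed the edgeR test, 6160 higher (46.5%) and 7078 lower. The split moved with the scaling: with plain library sizes, added after seeing the data, 4181 of 14103 called genes were higher (29.6%) and the median of all genes shifted by -1.40, and the shifts were 0.318 with median-ratio and -0.388 with upper-quartile factors. The majority turned with median-ratio factors, with 6759 higher and 6388 lower (51.4% higher), and with DESeq2, with 7092 higher and 6317 lower (52.9% higher). Against the same day 7 libraries, pachytene called 12673 genes. Of these, 5348 rose and 6064 fell in both comparisons and 98 went opposite ways, where independent lists would share 2160 and 2835. Independence is a weak standard here, as both fractions were set against the same mixed tissue. Part of the excess may come from the shared day 7 libraries. Simulated groups with no gene changed shared at most 1 call, which cannot gauge the overlap, since few genes are called when none change.

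From leptotene/zygotene to pachytene, some transcripts of the piRNA pathway rose and most of those of spermatids fell. Piwil1 went from 129 ± 11.9 to 1181 ± 404 CPM (log2 fold change 3.20 ± 0.31, adjusted p = 0.000755). Tdrd5 rose by 3.01 ± 0.36, Tdrd1 by 2.67 ± 0.37 and Pld6, which cuts piRNA precursors, by 2.27 ± 0.28. Prm1 went from 8051 ± 3608 to 731 ± 61.1 CPM (-3.46 ± 0.96, adjusted p = 0.0303), Tnp1 fell by 3.45 ± 0.88, Tnp2 by 3.48 ± 0.98 and Tssk6, a sperm kinase, by 3.38 ± 0.33. The highest-ranked rises were of A030009H04Rik, Gm15545, 2610001J05Rik, 4930579G24Rik and Sap30 (3.53 to 3.61). The highest-ranked falls were of Beta-s, a beta-globin (-5.50 ± 0.57), Tnf, an inflammatory cytokine (-4.26 ± 0.91), Slc18a3, the acetylcholine transporter of vesicles (-4.15 ± 0.56), Traf1 (-3.84 ± 0.57) and Olfr733 (-3.79 ± 0.53).

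Of 23 piRNA genes 8 rose and none fell in both counts, with a median of 0.87 (camera adjusted p = 2.72e-06; adjusted p = 0.673 with an estimated correlation), a list call kept without each library in turn. Of 32 spermatid genes 19 fell and none rose (27 adjusted over the list alone), with a median of -2.08 (adjusted p = 1.01e-09; adjusted p = 0.673 with an estimated correlation). The call of Tssk6 was not lost without any library, whereas those of Prm1, Tnp1 and Tnp2 were each lost without either pachytene library (adjusted p of 0.0861 to 0.134) or either day 1 library, and those of Prm1 and Tnp2 also without either day 7 or the second leptotene/zygotene library. Of 37 meiotic prophase genes 7 rose and 2 fell in both counts. Tex12, of the synaptonemal complex, rose by 3.27 ± 0.56 and Spata22, of meiotic recombination, by 2.90 ± 0.48, while Syce2 fell by 2.42 ± 0.32 and Tex15 by 2.05 ± 0.45; Sycp3 rose by 1.73 ± 0.39. Of 29 crossover and pachytene genes 6 rose and 2 fell (3 adjusted over the list alone), among them Cdk2 (2.46 ± 0.27), Ccnb1ip1, also called Hei10 (3.40 ± 0.73), and Calr3, a testis chaperone (-2.74 ± 0.34). Without the second leptotene/zygotene library Tex12 and Ccnb1ip1 were no longer called, and without a pachytene library neither were Tex15 (either), Sycp3 or Tnf (the second). Of 31 cell cycle genes 5 rose, such as Ccne2 by 2.44 ± 0.42 and Cdca8 by 1.76 ± 0.34, and Cdkn1c and Ccnd3 fell (7 and 2 adjusted over the list alone).

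Markers of other cells moved in both directions beside these groups. Of 22 Sertoli genes 6 were higher in pachytene, including Clu (45.1 ± 34.5 to 155 ± 14 CPM) and Inhbb (2.14 ± 0.51), both no longer called without the first pachytene library, Clu also without the second and Inhbb without the second leptotene/zygotene library, with the list higher by camera (adjusted p = 0.00677; adjusted p = 0.731 with an estimated correlation; lost without the second leptotene/zygotene library, adjusted p = 0.187). Of 15 macrophage genes 7 fell (8 adjusted over the list alone): C1qb, of the complement system, went from 38.7 ± 16.1 to 4.50 ± 2.85 CPM and Aif1 from 506 ± 150 to 87.5 ± 5.41. C1qa and C1qc fell from 17 and 16 counts to 2 each. Aif1 did not follow most of the list, as it had risen from day 7 to leptotene/zygotene, where 10 of the 15 fell. That list was lower (adjusted p = 0.00351; adjusted p = 0.673 with an estimated correlation; lost without the first leptotene/zygotene library, adjusted p = 0.15). Hemgn fell by 2.42 ± 0.40 and Dcn, a matrix proteoglycan, by 3.79 ± 0.54, and 2 other matrix genes of 24 fell. Leydig markers Hsd3b1, Hsd3b6 and Insl3 rose, of 14 tested (7 rose and 1 fell adjusted over the list alone).

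X-linked genes were called lower more often than autosomal ones here too. Of 686 tested 143 fell and 11 rose (20.8% lower against 12.7% of autosomal genes), and the median lay 0.56 below, at -0.61 against -0.05 (camera p = 0.000206; p = 0.448 with an estimated correlation). Uba1, the ubiquitin-activating enzyme, fell by 1.64 ± 0.24 and Cstf2 by 1.53 ± 0.31, among 6 of 34 genes of the fixed list (5 adjusted over the list alone; adjusted p = 0.0906). Without the first leptotene/zygotene library the X-linked genes were no longer called lower as a set (difference of medians -0.12), nor were they without the second pachytene library (-0.08).

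Between these fractions 3715 of 16872 genes passed the edgeR test, 1504 higher in pachytene (40.5%) and 2211 lower. With plain library sizes 3693 of 4790 called genes were higher (77.1%) and the median of all genes shifted by 0.554, so the direction of the whole depends on the scaling. The genes refitted one by one, given last, include fixed genes such as Stra8 and Dmc1 that had no call to lose. Without the second leptotene/zygotene library 2052 passed, and without the first or second day 7 library or the first pachytene library 2385, 2389 and 2377. Of 69 genes refitted one by one, 12 lost their call without either day 1 library, 11 without either day 7 library, 14 without the second leptotene/zygotene library, and 13 and 17 without the first and second pachytene library.

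miRNA families were counted by seed, the 7 bases at positions 2 to 8 of the mature miRNA that pair with targets. From day 1 to day 3 no family of 745 passed the edgeR test, while 151 had an unadjusted p under 0.05 and DESeq2 called 58. That fit also drew its spread from the spermatocyte stages, whose replicates varied more. A fit of the testis stages alone, chosen after seeing the data, called 129 families, and a fit of only the stages compared called 32. The count of 0 thus depends on the stages fitted and does not show that no family changed. The seed of miR-10 made up 37.3% of counts on day 1 and 31.3% on day 3. The largest shortfalls among the families fixed by name were miR-290-5p, of a cluster active in embryonic stem cells (-2.17 ± 0.43), and miR-871-5p (-1.85 ± 0.41), both at an adjusted p of 0.0833. The let-7 family, which favours differentiation, was at 52810 ± 6770 and 43480 ± 2015 CPM. Counts above 0 arose without single libraries: 29 without either leptotene/zygotene library, 21 without the first day 3 or first pachytene library, 13 without the first day 1 and 5 without the second day 3 library.

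From day 3 to day 7 families of the X-chromosome miRNA cluster near Fmr1, which is active in the testis, rose. Of 14 tested families 10 rose and none fell (14 adjusted over the list alone), with a median of 2.74 (camera adjusted p = 6.78e-13; adjusted p = 0.323 with an estimated correlation). miR-470-5p went from 1171 ± 255 to 8069 ± 287 CPM (2.79 ± 0.52, adjusted p = 0.00574), miR-465-5p from 391 ± 138 to 2549 ± 158, and miR-465-3p, miR-881-3p and miR-743-3p rose by 2.97 ± 0.47, 2.79 ± 0.46 and 2.79 ± 0.63. Seeds left without a name here that rose were ACCUAAU (3.20 ± 0.57), AAGACAU (3.20 ± 0.69) and GAUCAGG (2.86 ± 0.50), and GGUUACC fell by 2.52 ± 0.51. GAUCAGG and AAGACAU are the seeds of miR-465-3p (AUCAGGG) and miR-743-3p (AAAGACA) shifted by a base, so they may not be separate families. GAUCAGG had 8677 counts over both day 7 libraries and 1610 over those of day 3, against 9524 and 1639 for AUCAGGG. The 16 families of the imprinted Dlk1-Dio3 cluster had a median of -0.79 (adjusted p = 0.000774; adjusted p = 0.406 with an estimated correlation) with none past the test. miR-29 was at 58 ± 3.07 and 144 ± 5.29 CPM and miR-202-5p at 3233 ± 108 and 7278 ± 741.2 (adjusted p = 0.226 for both).

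In all 38 of 745 families passed, 33 higher (86.8%) and 5 lower. With median-ratio factors 79 passed, 31 higher (39.2%), as the median family shifted by -0.317; plain library sizes shifted it by 0.151 and called 54, 52 of them higher, and DESeq2 called 90, 30 of them higher. Without the first day 3 library 20 passed (10 higher), and miR-470-5p, miR-465-5p, miR-881-3p, miR-743-3p and AAGACAU were no longer called; without the first or second day 7 library 22 passed, and without the first day 1 library 63 and the first leptotene/zygotene library 90.

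**Figure D2:**
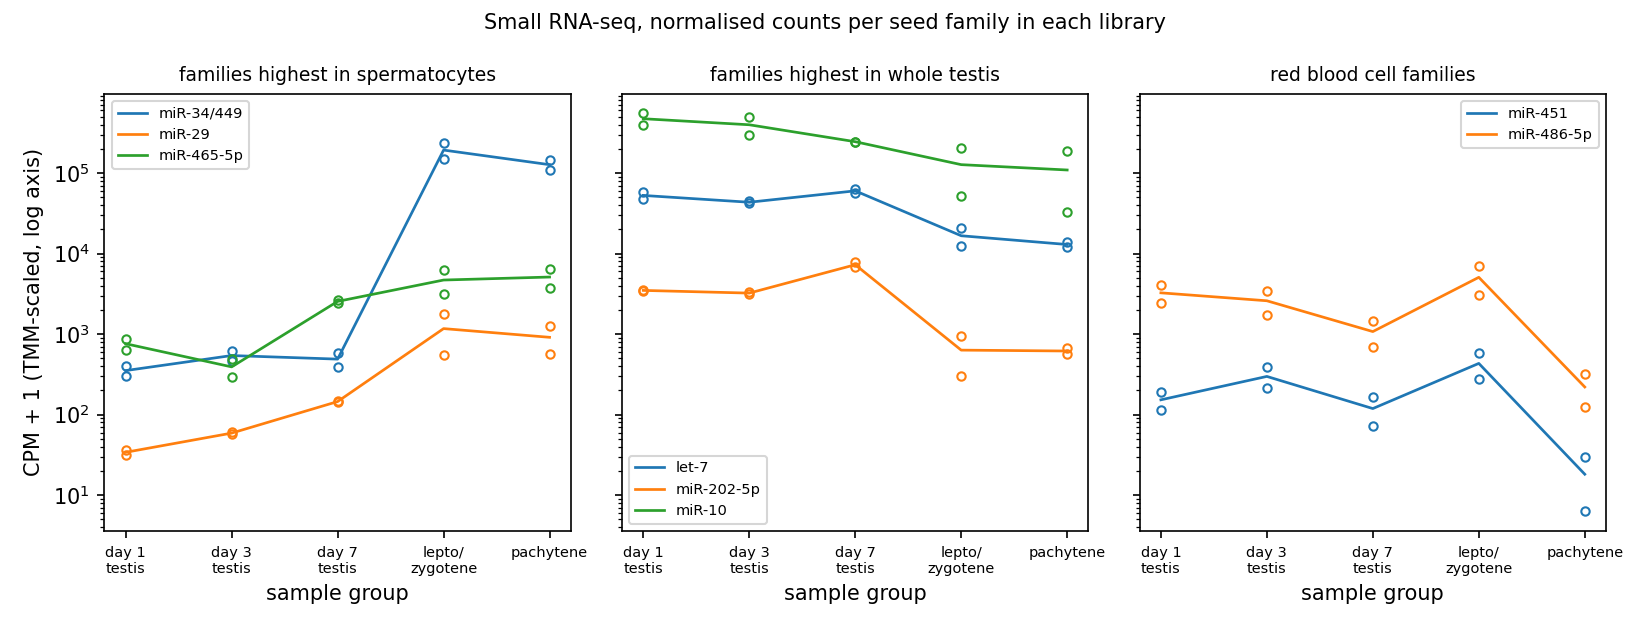
Levels of 8 miRNA families at the 5 stages in 3 panels, as CPM + 1 on a log axis; open circles are single libraries (2 per stage) and lines join the stage means. The miR-34 and miR-449 family went from 488 CPM at day 7 to 193300 in leptotene/zygotene, and miR-451 and miR-486-5p were lower in pachytene than in leptotene/zygotene.

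In leptotene/zygotene spermatocytes the miR-34 and miR-449 family, known for its role in male germ cells, was the most abundant, at 22.9% of counts. It also had the highest mean level in pachytene, at 17.7% of counts (SD 9.45). It rose from 488 ± 136 to 193300 ± 61030 CPM against day 7 (log2 fold change 8.63 ± 0.62, adjusted p = 1.2e-06). The let-7 family fell by 1.85 ± 0.43 and miR-202-5p, a family of Sertoli and early germ cells, by 3.51 ± 0.54 (7278 ± 741.2 to 632 CPM). miR-29 rose by 3.03 ± 0.59, from 144 ± 5.29 to 1171 ± 878 CPM (adjusted p = 0.000755). miR-10 was at 245500 ± 1439 and 127400 ± 107300 CPM (adjusted p = 0.267). Spermatid transcripts were abundant in the RNA libraries of this fraction. Whether its small RNA also came in part from later cells was not tested.

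Of the 14 families of the X cluster 11 rose in both counts (median 2.48, camera adjusted p = 0.00331; adjusted p = 0.649 with an estimated correlation), among them miR-743-3p by 3.25 ± 0.64, miR-741-3p by 2.75 ± 0.55 and miR-881-3p by 2.35 ± 0.45. Of 16 families of the Dlk1-Dio3 cluster 15 fell (16 adjusted over the list alone; median -4.36, adjusted p = 2.08e-06; adjusted p = 0.132 with an estimated correlation). The miR-199 and miR-214 families of fibroblasts fell, 3 of 3. Of 6 leukocyte families 4 rose and of 3 erythroid families 2 rose (3 adjusted over the list alone), while miR-335-5p fell by 5.88 ± 0.63. Unnamed seeds with no count at day 7 included CUCCAGC (at least 3190-fold higher), CCAUGAA (at least 2850-fold), UGAGACA (at least 1130-fold), UUCUGGG (at least 810-fold) and AUCUUGU (at least 641-fold), and AACAUUG went from 1.54 ± 0.36 to 15770 ± 11010 CPM. miR-18 and miR-19 of the miR-17 cluster rose by 2.06 and 1.09, miR-26-5p and miR-221 and miR-222 fell, and miR-17 and miR-21-5p were not called (adjusted p = 0.25 and 0.466).

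Of 745 families 465 passed, 185 higher and 280 lower (39.8% higher); with upper-quartile factors 47.9% of the called families were higher, and the median family shifted by 0.548, and by 0.381 with median-ratio factors. Without the first leptotene/zygotene library 234 passed, and with every library thinned to the smallest total, an alternative chosen after seeing the data, 29 of 371 tested did (22 higher, 7 lower). DESeq2, fitted without the filter, called 408, 210 higher and 198 lower. The families refitted one by one, given next, include fixed families such as miR-10 and miR-143-3p that had no call to lose. Of 38 families refitted one by one, 4 lost their call without the first leptotene/zygotene library (miR-290-5p and, of the X cluster, miR-463-3p, miR-742-3p and miR-878-3p), 4 without the first day 7 library (miR-290-5p, miR-292-3p, miR-871-5p and miR-878-3p) and 3 without the second (the same without miR-871-5p). miR-290-5p also lost its call with median-ratio or upper-quartile factors, while let-7, miR-202-5p, miR-29 and the miR-34 and miR-449 family kept theirs in each refit.

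Between leptotene/zygotene and pachytene 3 of 745 families passed. miR-486-5p and miR-451, both abundant in red blood cells, went from 5078 ± 2792 to 220 ± 138 CPM (-4.51 ± 0.69, adjusted p = 0.0111) and from 432 ± 222.5 to 17.2 ± 16.8 (-4.49 ± 0.78, adjusted p = 0.0129). The erythroid list, with 2 of 3 families lower (3 adjusted over the list alone), was lower by camera (adjusted p = 4.42e-07) and stayed so with an estimated correlation (adjusted p = 0.0254). The seed GAAGGGG rose by 3.37 ± 0.51. miR-34 and miR-449 (-0.60 ± 0.44, adjusted p = 0.625) and miR-29 (-0.36 ± 0.55, adjusted p = 0.857) did not pass, and none of the 14 families of the X cluster did.

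At this step 89 families had an unadjusted p under 0.05, DESeq2 called 21, and the 2 smallest libraries of the series, of 119746 and 112967 counts, were among the 4 compared. Without the first pachytene library none passed, and without the first leptotene/zygotene library 1 did; miR-451 was also lost without the second pachytene library. Of simulated families changed 4-fold at this step the test recovered 16.7%, and of those changed 2-fold 3.57%. These were drawn with a spread common to all stages, although replicates varied more in the spermatocyte stages.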

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

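The tests on spermatid transcripts in the purified fractions were written after the result was seen except the one on early recombination genes, while those on miR-29 targets and on traces in the pup libraries were written before their values were calculated; the rule on unaligned reads was set after seeing the data.

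Reads that did not align made up 39.2% of the first leptotene/zygotene RNA library and 42.1% of the first pachytene RNA library, against 13.3% to 19.9% in the other RNA libraries. What these reads hold was not tested. Without both of these libraries a single library per fraction remained, so a count of genes called would rest on the spread of the testis stages alone. The median log2 fold change of all genes between the fractions was then -0.265, and 0.047 without both of the second libraries, against -0.0621 with all libraries.

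Transcripts of spermatids were abundant in the leptotene/zygotene libraries and lower in pachytene, the reverse of the order in which cells mature. For swapped labels the test written in advance was that early recombination genes have a positive median towards pachytene. Its criterion was met, at 0.212 with 3 of 12 called higher and none lower. That median was small against their spread (median absolute deviation 1.54), a measure not set in advance. The test chosen afterwards argues against a swap. The piRNA pathway list is known to rise in pachytene, and 8 of its members were called higher there and none lower. As these tests disagree, a swap is not settled. Scaling does not account for the reversed order, as the highest of the spermatid list's medians under 4 scalings was -1.484. Spermatids, or RNA released from them, in the leptotene/zygotene fraction may explain it, with 59.4% of the list called lower in pachytene, but this cannot be told apart from transcripts made early by the spermatocytes themselves.

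Spermatid transcripts were also found at low levels in newborn testes, which hold no spermatids. Of 83 genes with at least 500 CPM in leptotene/zygotene and at most 1 count at day 7, 83.1% had a ratio of day 1 to leptotene/zygotene within 2-fold of the median ratio, 0.0621%. In the single day 1 libraries this share was 78.3% and 71.1%. The genes were picked by these levels and not from the spermatid list, and no other set of genes was used as a reference. A common ratio is what carried-over adult germ cell RNA or reads would give, whereas expression by the newborn testis itself would not be tied to the adult levels gene by gene. The summed levels were 98.61 and 107.4 CPM in the day 1 libraries, 2.698 and 91 in those of day 3 and 0.681 at day 7, so the lower spermatid list at day 3 rests on the first day 3 library and the lower one at day 7 on the second. The raw reads were not examined, so a carry-over was not shown directly. Whether it would have happened at the bench, in sequencing or in the counting was not tested.

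Lists of miR-29 targets were lower in leptotene/zygotene, where miR-29 was higher. Targets outside the matrix were lower by camera (p = 0.0017; p = 0.342 with an estimated correlation), which may reflect repression by miR-29, but this cannot be told apart from the loss of somatic cells at the same step. Matrix genes that are not on the target list had a median of -4.68, against -5.13 for the matrix targets, which is in line with the loss of the cells that make matrix.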

How the results depend on the processing

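Plain library sizes, fits of the testis stages alone, thinning, leaving out both spermatocyte libraries with the same number, pachytene against day 7 and the refits of named genes were chosen only after results were seen. Upper-quartile factors for the lists and X-linked genes were not planned either. The other alternatives were planned. Fits without both spermatocyte libraries of the same number left a single library per fraction. Their counts below thus rest on the spread of the testis stages, whose replicates differed less. With plain sizes 145 of the 13238 genes called from day 7 to leptotene/zygotene were called in the opposite direction, as was 1 of 38 families from day 3 to day 7 after thinning, and the cause was not tested for any change below unless given.

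For RNA from day 1 to day 3, where 0 genes passed, 7 did in the fit of the testis stages alone, 75 with DESeq2, and 0 to 35 with a library left out (35 without the second day 3 library). From day 3 to day 7, where 250 passed, the count was 396 with no filter, 2168 with the testis stages alone, 983 with only the stages compared, 26 against a 2-fold minimum and 965 with DESeq2, and 0 (without either day 7 library) to 609 (without the second leptotene/zygotene library). Of the 250, 248 kept their call and direction with DESeq2, but 34 without the first day 3 library and 118 without the second. From day 7 to leptotene/zygotene counts stayed between 10953 (2-fold minimum) and 14278 (without both spermatocyte libraries numbered 1). Between the fractions, where 3715 passed, the count was 2316 without both libraries numbered 2, 823 with only the stages compared, 916 against a 2-fold minimum, and 2052 (without the second leptotene/zygotene library) to 5054 (without the first).

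For small RNA from day 1 to day 3, where 0 families passed, 16 did with median-ratio factors, 67 with no filter, 129 with the testis stages alone, 3 after thinning, 32 with only the stages compared, 58 with DESeq2, and 0 to 29 with a library left out. From day 3 to day 7, against 38, the counts were 79 with median-ratio factors, 115 with the testis stages alone, 4 after thinning, 123 with only the stages compared, 22 against a 2-fold minimum, 90 with DESeq2, and 20 (without the first day 3 library) to 90 (without the first leptotene/zygotene library). From day 7 to leptotene/zygotene, against 465, they were 29 after thinning, 276 without both spermatocyte libraries numbered 1, and 234 (without the first leptotene/zygotene library) to 486 (without the first pachytene library). Between the fractions, against 3, they were 6 with median-ratio factors or plain sizes, 14 with no filter, 0 after thinning or without both libraries numbered 1, 43 without both numbered 2, 21 with DESeq2, and 0 (without the first pachytene library) to 8 (without the first day 1 library). Thinning to 112967 counts also cut the families tested from 745 to 371.

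The lower X-linked genes (differences of -2.61 at day 7 to leptotene/zygotene and -0.558 between the fractions) were no longer called with an estimated correlation, and between the fractions, pachytene against leptotene/zygotene, the value for X-linked genes ran from -1.12 (without the first pachytene library) to -0.0754 (without the second). The directional fry test does not set a list against other genes. With it 9 gene list calls were lost from day 1 to day 3 and 8 from day 3 to day 7. From day 7 to leptotene/zygotene 5 were gained and the other 15 lists were unchanged. Between the fractions the unadjusted fry p was 0.00901 for the piRNA, 0.00726 for the spermatid, 0.00459 for the macrophage and 0.0622 for the Sertoli list.

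Replicate numbers were not treated as paired: across genes the replicate differences of the 2 fractions correlated for RNA (r = 0.583; -0.095 to 0.0228 between other stages), while for small RNA r was 0.141, close to the -0.119 to 0.12 between other stages. With the number as a block 0, 253, 13191 and 3656 genes passed in the order of the stages, and 0, 30, 438 and 3 families. The block is a single effect shared by all stages, so it cannot take up a pairing of the fractions alone. No paired test of the fractions was run, so these counts do not show whether pairing matters. The planned analysis of genes with seed sites was not run, as transcript 3′ ends were not used here.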

Other observations

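No test of this part was chosen, before or after results were seen.

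Families among the 5 most abundant at some stage included miR-143-3p, at 10.7% of counts in leptotene/zygotene, miR-191-5p, at 9.06% in pachytene, and miR-127-3p, at 7.22% on day 3. Hba-a1 and Hba-a2, the alpha-globins, had 0 counts in every library, whereas Beta-s had counts in all 10.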
